A study of Mus musculus with 10 samples.

How the data were processed

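A total of 10 libraries were analysed, 5 labelled as Ovgp1 knockout aorta and 5 as wild-type aorta, grouped by their titles. Per the labels' protocols, aortas were frozen, RNA was extracted with Trizol, and libraries were made from 1 ug of total RNA with the Illumina TruSeq RNA kit. The deposited files hold whole-number read counts per gene, with 35667 Ensembl genes in the same order in each. The submitters' processing notes name Bowtie 0.12.2 and the builds mm8 and mm9, with no roles. The Ensembl identifiers are of the GRCm38 period, which does not match those builds. The counting tool, the annotation and the strand setting are not given in the sources used here, so overlapping or antisense genes may share reads. Coordinates and biotypes come from a match of the identifiers to GENCODE M21 (GRCm38), which found 35519 of 35667.

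Depth ran from 21242030 to 26694590 counts per library. Intervals and SDs of the libraries labelled KO cover little beyond counting error. The main test was the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3) with robust estimation, TMM normalization and filterByExpr (minimum count 10, minimum total 15), comparing 5 KO with 5 WT libraries without a covariate. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05, and each adjusted p of a gene is from this test. The standard error is the log2 difference divided by the square root of F. Values in CPM are TMM-scaled.

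Before the data were examined, 41 gene lists with 746 members were written for aortic cell types, matrix, contraction, adhesion, signalling, metabolism, stress, time of day and other tissues. Matching by symbol found 743, and 39 lists had at least 3 tested members. Lists were tested with camera (limma 3.58.1, inter-gene correlation 0.01), with an estimated correlation and with fry. A score per library, the mean log2 CPM of tested members at a prior count of 2, was compared by a two-sided exact permutation test over all 252 splits. The named genes were fixed in advance by rule. They are Ovgp1 and Myh9, the 12 greatest positive and 12 greatest negative differences among protein-coding genes past the threshold with mean log2 CPM of at least 1, up to 4 members of smallest p per list, the 2 most abundant members of lists of other cell types, and genes past the threshold within 2 Mb of Ovgp1. Some genes that the rule names are not reported here. Genes that passed with KO as 1 sample, Gm15446, Nnt and Rplp0 were named after their values were seen.

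Agreement within groups was checked with a chi-square of counts over genes with a mean of at least 50 counts. Because the libraries labelled KO were nearly identical, their counts were also summed into 1 sample and compared with 5 WT libraries in the same kind of fit, which takes its spread from the WT libraries alone. Both fits were tested on simulated data with genes changed by known folds. Each gene was drawn independently of the others, so variation that libraries share across genes was not simulated. The recovery given below need not hold in these data, where a missing call does not exclude a large difference. With 5 independent samples per group, 8 of 168 calls were unchanged genes. With 1 KO source in 5 libraries, the 5 against 5 fit called 3392 unchanged genes among 3582 calls over 15283 genes, and the summed fit called 13 among 113. The summed fit recovered 4%, 22%, 78% and 96% of genes changed 1.5-, 2-, 4- and 8-fold.

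Alternatives were other size factors, other filters, a replicate block, leaving out each library, leaving out genes of 7 lists of other tissues, DESeq2 1.42.0, limma-voom with sample weights, 1 surrogate variable (sva 3.50.0), a fold of 1.2 in the test, and other set tests. No library was left out of the main fits.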

Results

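Gene expression was measured by RNA sequencing in 10 libraries from mouse aorta, the main artery leaving the heart, of C57BL/6 animals aged 12 weeks. Of the libraries, 5 were labelled knockout (KO) for Ovgp1, which encodes oviductal glycoprotein 1, a secreted chitinase-like protein, and 5 were labelled wild type (WT). The titles and the design name Ovgp1 for all 5 KO libraries, but the genotype field names Ovgp1 only for KO replicate 1 and Ovgp2, Ovgp3, Ovgp4 and Ovgp5 for KO replicates 2 to 5. The title of the series asks about Ovgp1, remodelling of the vessel wall, blood pressure and the product of Myh9, non-muscle myosin heavy chain IIA. Total counts per library ran from 24434745 to 26694590 among those labelled KO and from 21242030 to 24396394 among those labelled WT. Of 35667 genes, 15710 had enough counts to be tested. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had at least 206 counts in each of the 10 libraries, and Xist had 3 to 21.

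The 5 libraries labelled KO were nearly identical to each other, and those labelled WT were not. Over 12509 genes with a mean of at least 50 counts, the chi-square per degree of freedom between 2 libraries, which is 1 where only counting error separates them, was 1.77 to 3.25 for the 10 pairs labelled KO. It was 11.0 to 154 for the 10 pairs labelled WT. The biological coefficient of variation was 2.83% within KO and 21.3% within WT. No label says that libraries of a group came from separate animals. The KO pairs still differed by slightly more than counting error, which does not show that they came from separate animals. The 5 against 5 comparison is given as the planned result only because it was fixed in advance. P-values from it measure the spread between these libraries, which in KO was close to technical, and the SD of a KO value covers little beyond counting error. Beside it stands a fit, chosen after seeing the data, in which the KO counts were summed into 1 sample and assumed to vary as the WT libraries do.

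**Figure D1:**
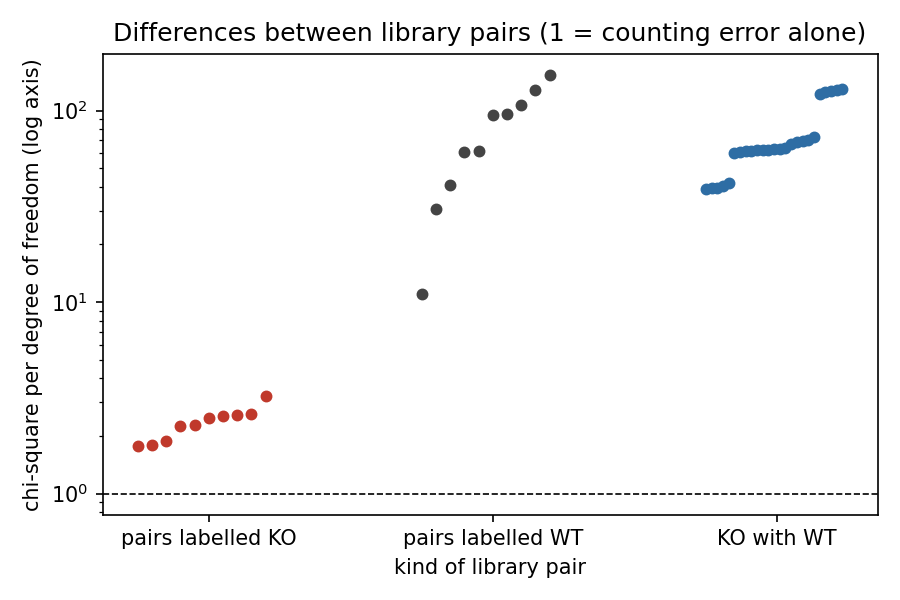
Chi-square per degree of freedom for each pair of libraries (log axis), with 1 point per pair and a dashed line at 1, the value of counting error alone. The 10 pairs labelled KO lie between 1.77 and 3.25, and the 10 pairs labelled WT between 11.0 and 154.

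Ovgp1 (ENSMUSG00000074340; chromosome 3, 105973711 to 105987423 in GRCm38), the targeted gene, was higher, not lower, in the libraries labelled KO. It had 19.4 ± 1.66 CPM (counts scaled to library size; SD, n = 5) there and 1.98 to 4.69 CPM in the libraries labelled WT. The fold was 5.28 (95% interval 3.93 to 7.09), with a log2 difference of 2.40 (SE 0.18, adjusted p = 2.84e-05). All 5 KO libraries lay above all 5 WT libraries (two-sided exact permutation p = 0.00794, the smallest that 252 splits can give). If the KO libraries repeat 1 source, any value outside the WT range gives that p, and chance puts 33.3% of genes there for 1 independent KO sample. In these data all 5 KO libraries lay above all 5 WT libraries for 7.38% of tested genes and below them for 7.22%. With KO as 1 sample the fold was 5.26 (95% interval 2.67 to 10.4) and the adjusted p was 0.217. The counts sum over a gene, and the labels do not say which part of Ovgp1 was targeted, so they do not show whether the transcript was intact. Every direction given here follows the labels, which this gene goes against.

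Myh9 (ENSMUSG00000022443; chromosome 15, 77760587 to 77842175) had 648 ± 10.7 CPM in the libraries labelled KO and 634 ± 105 CPM in those labelled WT (SD, n = 5 each). The log2 difference was 0.03 (SE 0.10, adjusted p = 0.876; exact permutation p = 0.810), and the 95% interval of the fold was 0.87 to 1.2. With KO as 1 sample that interval was 0.65 to 1.61, so a change of that size in Myh9 was not excluded.

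**Figure D2:**
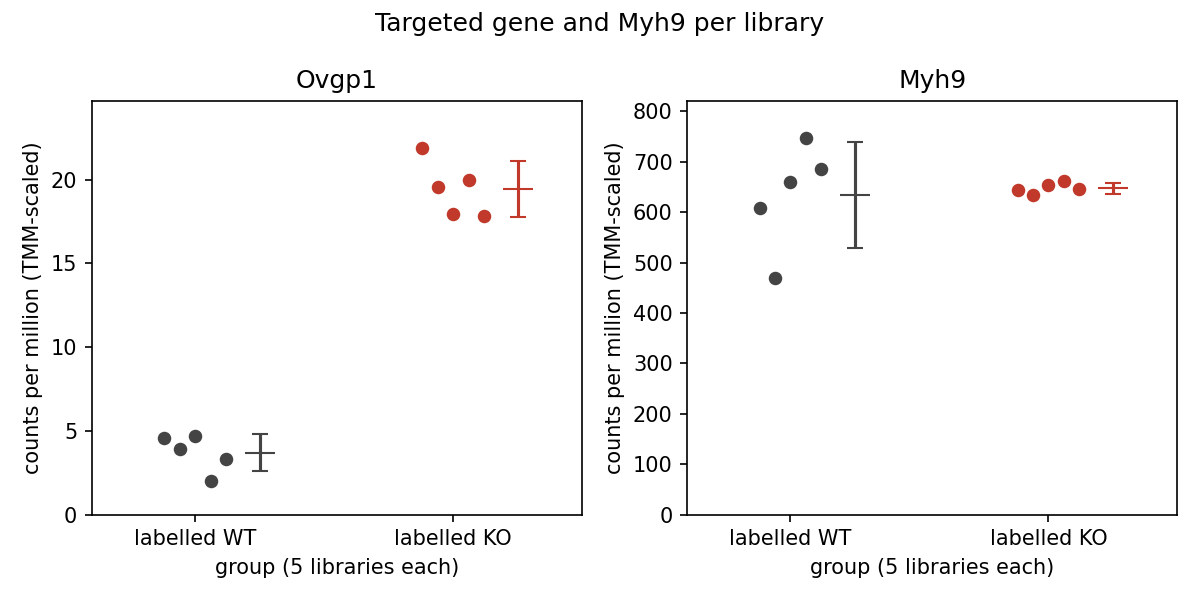
Ovgp1 and Myh9 in CPM per library, with points for the 5 libraries of each group and a bar at the mean ± SD. Ovgp1 lies at 17.8 to 21.9 CPM in the libraries labelled KO and at 1.98 to 4.69 CPM in those labelled WT, while the Myh9 values of the groups overlap.

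In the planned test the antibody genes Ighm, Igkc and Jchain and the nerve genes Dbh, Th and Mbp were higher in the libraries labelled KO, and the haemoglobin genes Hba-a1 and Hbb-bs lower. In that test 2242 genes passed an adjusted p of 0.05, 1075 higher and 1167 lower, of which 166 and 78 differed by at least 2-fold. In the fit with KO as 1 sample 7 genes passed, all higher: Ighm, Ighg2b, Igkv4-91 and Ighv1-72, which encode parts of antibodies, the matricellular gene Sparcl1, and the processed pseudogenes Gm8730 and Gm9625. At an unadjusted p under 0.05 that fit held 585 genes, 3.72% of those tested, fewer than the 5% expected where no gene differs. Igkv4-91 and Ighv1-72 had 0 or 1 count in each WT library, against 99 to 131 and 63 to 95 in the libraries labelled KO. Leaving out any of the 5 KO libraries lowered the planned count to between 1287 and 1393. Leaving out any of the 5 WT libraries from the fit with KO as 1 sample left 1 to 5 genes (2 without replicate 1, 5 without replicate 2, 1 without replicate 3, 2 without replicate 4 and 1 without replicate 5). In simulated data with KO drawn from 1 source and sequenced 5 times, the planned test called 3392 unchanged genes, 94.7% of its calls, so a count of this size can arise with no effect of the genotype where a group is 1 source.

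Among protein-coding genes past the planned threshold with a mean log2 CPM of at least 1, the 12 with the greatest excess in KO included Jchain, Ovgp1, Chp2, Slc4a10, Sparcl1, Pla2g2d, Dbp, Tnr, Gdf10, Ciart and Serinc2. Jchain, which joins antibody units into polymers, had a log2 difference of 4.05 (SE 0.30). Sparcl1 was the most abundant, at 2410 ± 30.2 against 764 CPM, with a log2 difference of 1.66 (SE 0.08) and an adjusted p of 0.0413 with KO as 1 sample. The others named did not pass in the fit with KO as 1 sample. The 12 with the greatest deficit were Hba-a1, Hbb-bt, Hbb-bs, Nr4a3, Gm10800, Gm10801, Mt1, Gm21738, Ctla2a, Ctla2b, Mthfd2 and Arntl. Hba-a1 had a log2 difference of -3.32 (SE 0.43), the nuclear receptor gene Nr4a3 -2.77 (SE 0.53), and Mt1, a metal-binding metallothionein, -2.08 (SE 0.44). In counts, Nr4a3 had 449 to 493 in the libraries labelled KO, 829 and 516 in WT replicates 1 and 3, and 3504 to 4557 in WT replicates 2, 4 and 5. Mt1 had 5901 to 6443, 7995 and 6771, and 24343 to 44253. For both genes the difference thus came mostly from WT replicates 2, 4 and 5. Gm10800 had 821 to 1720 counts in the libraries labelled KO and 9722, 9878 and 3550 in WT replicates 1, 3 and 4. WT replicates 2 and 5 had 1372 and 1430, within the KO range. Counts of Gm10801 and Gm21738 were likewise highest in WT replicates 1 and 3 and within the KO range in WT replicates 2 and 5. None of these 12 passed with KO as 1 sample. Tnr, Gm10800, Gm10801, Gm21738 and Ctla2b lost their calls on leaving out any of the 5 KO libraries (adjusted p 0.0530 to 0.0927). They also lost them without a WT library: Tnr without replicate 2 (0.0517), Gm10800 (0.0526) and Gm10801 (0.0522) without replicate 1, Gm21738 without replicate 1 (0.0761) or 3 (0.0716), and Ctla2b without replicate 2 (0.0747), 4 (0.0772) or 5 (0.0820). Without the low-count filter these 5 (0.0969 to 0.164), Dbp (0.0515), Mt1 (0.0543) and Mthfd2 (0.0649) did not pass, with limma-voom Gm10800 (0.112) and Gm21738 (0.127) did not, and without WT replicates 1 and 3 Gm10800 did not (0.0918). Near-identical copies may share reads in Hba-a1 and Hba-a2, Hbb-bs and Hbb-bt, Ctla2a and Ctla2b, and the antibody genes, so their separate values are uncertain.

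Of 39 gene lists tested, 7 passed an adjusted p of 0.05 with camera at a preset correlation, 3 higher and 4 lower in the libraries labelled KO. The lymphocyte and the peripheral nerve list also passed with an estimated correlation, and 8 passed with KO as 1 sample, the 7 and the circadian list. That fit compares each list with other genes in 1 KO sample, so it does not show that other KO aortas would differ. In the planned 5 against 5 fit, the camera count rose from 7 to 12 without WT replicate 2 and to 11 without WT replicate 3. The other lists did not pass camera. By fry, which tests a list without comparing it with other genes, 7 lists passed: lymphocyte, peripheral nerve, red cell, fibroblast, circadian (adjusted p = 0.00500), cartilage (adjusted p = 0.000799) and kidney, adrenal and liver (adjusted p = 0.0325). The score per library passed for the same 7 lists and for the granulocyte and mast cell list and the elastic fibre list, each at an adjusted p of 0.0344 by exact permutation over 5 against 5 libraries. The unadjusted p of each was 0.00794, the smallest that these splits can give. If the KO libraries repeat 1 source, any list outside the WT range reaches that p, as 33.3% would by chance. Here 9 of the 39 lists did. The 2 mitochondrial lists and the glucocorticoid list passed neither fry nor the score test. The kidney, adrenal and liver list was lower in the libraries labelled KO, with 3 of 14 members tested and 1 of them, Alb, past the planned threshold. Alb lost its call on leaving out any of the 5 KO libraries (adjusted p 0.0517 to 0.0786). The granulocyte and mast cell list was higher, with 0 of 5 tested members past the threshold.

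Lymphocyte genes were higher in the libraries labelled KO. Of 13 tested members, 7 were higher and 0 lower, and 7 were higher adjusted over the list alone (camera adjusted p = 1.87e-14; adjusted p = 0.0137 with an estimated correlation). Ighm, the heavy chain of IgM, had 157 ± 1.45 against 9.35 ± 3.29 CPM, Igkc, the kappa light chain constant region, 95.6 ± 1.64 against 5.66 ± 3.52 CPM, and Jchain 22.8 ± 0.89 against 1.35 ± 0.80 CPM (SD, n = 5 each). Cd74, the invariant chain of MHC class II, differed less, at 58.3 against 38.8 CPM. With KO as 1 sample 1 member, Ighm, passed over all genes, and 6 passed adjusted over the list alone.

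Genes of Schwann cells and nerves were also higher in the libraries labelled KO, with 6 of 16 tested members higher, 0 lower and 9 higher adjusted over the list alone (camera adjusted p = 1.22e-13; adjusted p = 0.00426 with an estimated correlation). Dbh, which makes noradrenaline from dopamine, had a log2 difference of 4.70 (SE 0.31) at 3.39 against 0.12 CPM, and Th, the first enzyme of catecholamine synthesis, 3.01 (SE 0.41) at 2.15 against 0.27 CPM. The myelin gene Mbp had 20.3 against 8.89 CPM. The most abundant members, Ncam1 and Uchl1, had log2 differences of -0.16 and -0.03 and did not pass. In the fit with KO as 1 sample 0 members passed over all genes and 6 passed adjusted over the list alone.

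Red cell genes were lower, with 5 of 6 tested members lower and 5 adjusted over the list alone (camera adjusted p = 6.42e-08; adjusted p = 0.383 with an estimated correlation). Hba-a1 had 7.71 ± 0.33 CPM in the libraries labelled KO and 26.5 to 139 CPM in those labelled WT. Hbb-bs had 10.1 ± 0.62 CPM against 31.9 to 156 CPM. Hba-a2 had 0.53 against 7.61 CPM.

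Fibroblast genes were higher, with 7 of 17 members higher, 0 lower and 11 higher adjusted over the list alone (camera adjusted p = 2.45e-06; adjusted p = 0.383 with an estimated correlation). The proteoglycan genes Lum and Dcn had log2 differences of 0.84 (SE 0.07) and 0.36 (SE 0.08), Scara5 0.57 (SE 0.11), and Cd34, a surface marker of adventitial cells, 0.49 (SE 0.07). None of the 4 passed with KO as 1 sample.

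The remaining lists below their background were mitochondrial or hormone-responsive. Of 12 transcripts of the mitochondrial genome, 0 passed over all genes and 8 were lower adjusted over the list alone (camera adjusted p = 0.00448; adjusted p = 0.816 with an estimated correlation). For mt-Nd1 the values were 9124 ± 112 against 14082 ± 5582 CPM, and the log2 differences of mt-Nd2, mt-Co2 and mt-Co3 were -0.57, -0.85 and -1.06. The mitochondrial share of counts was 7.61% to 7.88% in the libraries labelled KO, 16.2% in WT replicate 1, 13.2% in WT replicate 3 and 6.75% to 9.59% in the other WT libraries. Without these 2 WT libraries, a step chosen after seeing the data, 4386 genes and 15 lists passed. Of 35 nuclear genes of oxidative phosphorylation, 6 were lower and 7 adjusted over the list alone (camera adjusted p = 0.00448; adjusted p = 0.816 with an estimated correlation). Cox4i1, Ndufb5, Atp5o and Uqcrb had log2 differences of -0.30, -0.32, -0.27 and -0.29. The score of this list was 6.53 to 6.58 in the libraries labelled KO and 6.60, 6.68, 6.49, 6.88 and 6.76 in WT replicates 1 to 5, with replicate 3 below every KO library (exact permutation adjusted p = 0.329; fry adjusted p = 0.157). The score of the brown adipocyte list was also lowest in WT replicate 3 (1.65) and highest in WT replicates 4 (4.96) and 5 (4.54), with 2.94 and 3.04 in WT replicates 1 and 2 and 3.23 to 3.30 in the libraries labelled KO. Of 12 glucocorticoid-responsive genes, 4 were lower and 6 adjusted over the list alone (camera adjusted p = 0.00448; adjusted p = 0.816 with an estimated correlation). These were Cdkn1a, a cell cycle inhibitor, at -1.16 (SE 0.14), Mt1, Errfi1 at -1.19 (SE 0.29), and Fkbp5, a chaperone of the glucocorticoid receptor, at -1.10 (SE 0.27). Errfi1 and Fkbp5 lost their calls on leaving out any of the 5 KO libraries (adjusted p 0.0551 to 0.0606) or WT replicate 5 (0.0508 and 0.0515), and Errfi1 also without WT replicate 2 (0.0553). Without the low-count filter Mt1 (0.0543), Errfi1 (0.109) and Fkbp5 (0.116) did not pass. None of the 12 passed over all genes with KO as 1 sample. The score of this list was 6.41 to 6.48 in the libraries labelled KO, 7.31 to 7.62 in WT replicates 2, 4 and 5, 6.63 in WT replicate 1 and 6.16 in WT replicate 3, which lay below every KO library (exact permutation adjusted p = 0.329; fry adjusted p = 0.182).

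**Figure D3:**
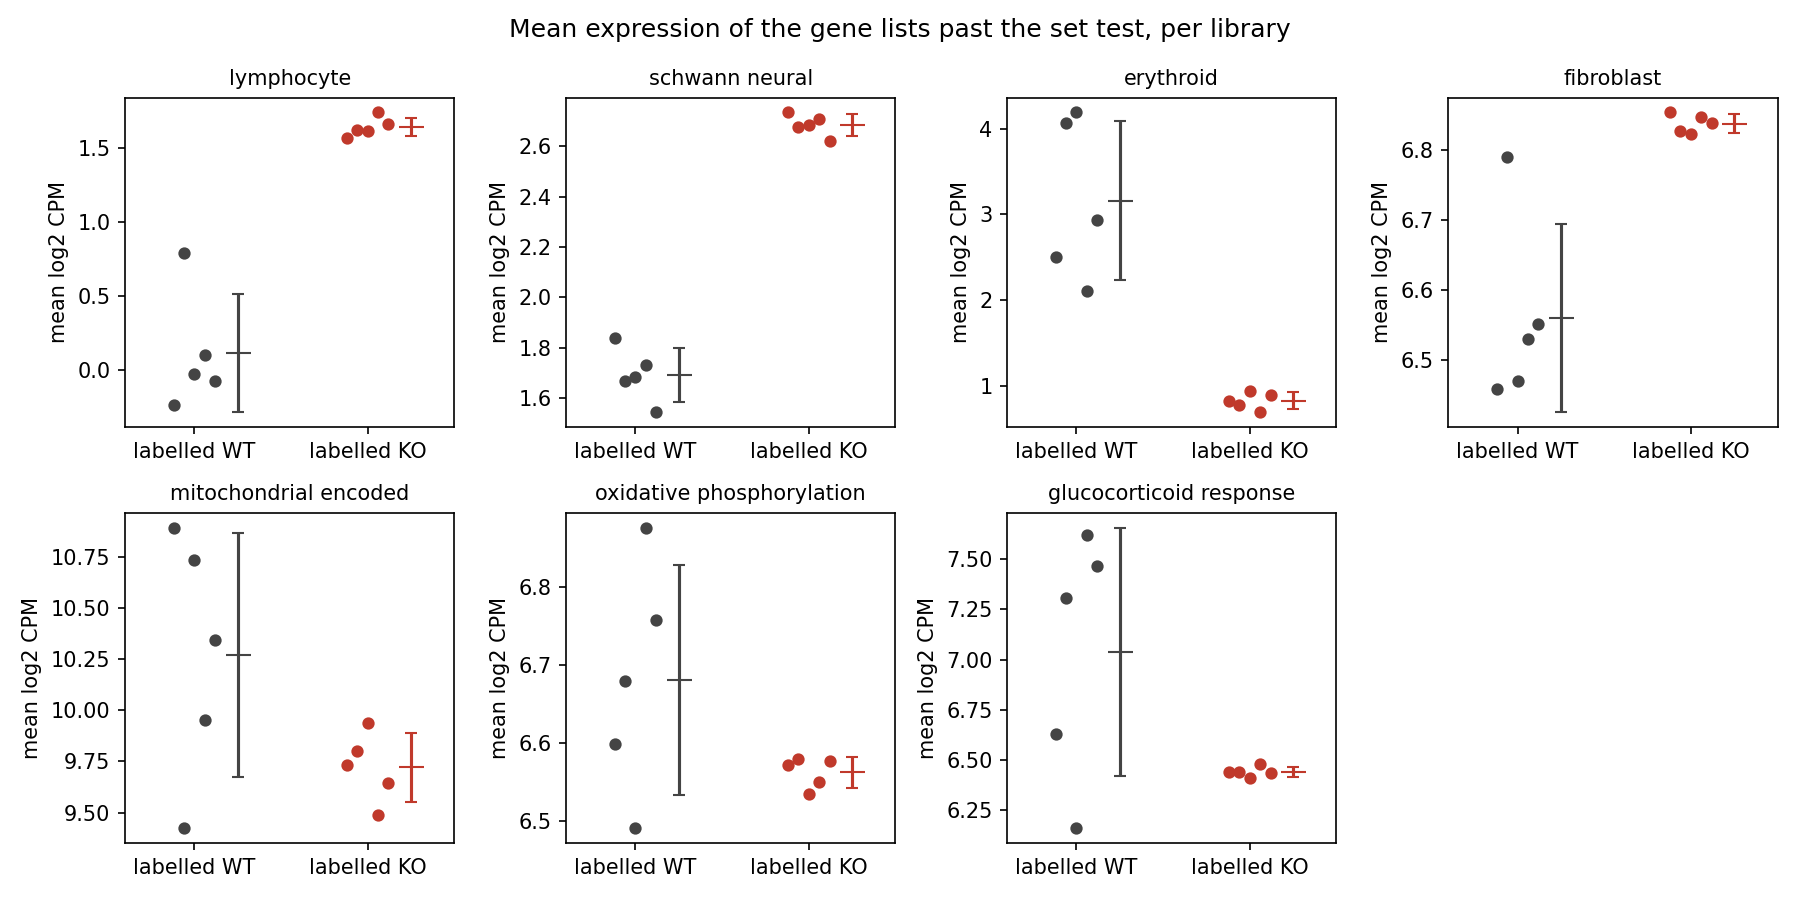
Mean log2 CPM of the members of each of the 7 lists that passed the set test, with points for the 5 libraries of each group and a bar at the mean ± SD. The lymphocyte list lies at 1.64 ± 0.06 in the libraries labelled KO and 0.11 ± 0.40 in those labelled WT, and the red cell list at 0.82 ± 0.10 and 3.16 ± 0.93.

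Clock genes differed in both directions. Of 19 tested members of the circadian list, 9 were higher and 5 lower in the libraries labelled KO, and 12 and 5 adjusted over the list alone (camera adjusted p = 0.0709; adjusted p = 0.383 with an estimated correlation; adjusted p = 0.0331 with KO as 1 sample, where 0 members passed). Arntl and Npas2, which activate transcription in the clock, had log2 differences of -1.40 (SE 0.16) and -1.23 (SE 0.15). Dbp, a clock output, had 1.56 (SE 0.34, adjusted p = 0.0515 without the low-count filter) and Ciart 1.47 (SE 0.28). The labels do not give the hour of dissection.

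Lists closest to the question of vessel wall remodelling did not pass camera. The camera and fry values in this report test for a shift in 1 direction. By fry for differences in either direction, the 6 lists below passed (adjusted p 4.01e-10 to 0.000852, 5 against 5 libraries). Lists of other cells passed that form too, such as macrophage (7.60e-05) and cartilage (4.94e-07). So did the lists of matrix proteases, modulated smooth muscle, basement membrane, vasoactive systems and ion channels (1.12e-07 to 0.00786). Those lists did not pass camera (adjusted p 0.128 to 0.602) and are not described further. Of 26 genes of actomyosin and its regulation, 1 was higher and 3 lower, and 1 and 3 adjusted over the list alone (camera adjusted p = 0.988): Myh10, another non-muscle myosin, at 0.46 (SE 0.09), Rock2, a kinase that acts on myosin regulation, at -0.29 (SE 0.06), and Rhoc at -0.26 (SE 0.07) were among them. Of 24 focal adhesion genes, 0 were higher and 1 lower, and 0 and 1 adjusted over the list alone (adjusted p = 0.720), the integrin gene Itga5 at -0.55 (SE 0.11). Of 22 contractile smooth muscle genes, 4 were higher and 1 lower, and 5 and 1 adjusted over the list alone (adjusted p = 0.197), with Mylk, myosin light chain kinase, at 0.32 (SE 0.05) and Sncg at 0.57 (SE 0.07). Of 25 elastic fibre and matrix genes, 7 were higher and 3 lower, and 10 and 3 adjusted over the list alone (adjusted p = 0.0978), with Fbln1 at 0.33 (SE 0.04) and Loxl1, an elastin cross-linking enzyme, at -0.35 (SE 0.05). The score of this list was 7.84 ± 0.0059 in KO and 7.71 ± 0.076 in WT (SD, n = 5; exact permutation adjusted p = 0.0344). The list did not pass with an estimated correlation (adjusted p = 0.816), by fry (adjusted p = 0.0702) or by camera with KO as 1 sample (adjusted p = 0.132). Of 16 collagens, 2 were higher and 0 lower, and 3 and 0 adjusted over the list alone (adjusted p = 0.425), with Col3a1 at 0.36 (SE 0.08) and Col8a1 at 0.80 (SE 0.23). Col8a1 lost its call on leaving out any of the 5 KO libraries (adjusted p 0.0789 to 0.0927) or WT replicate 1 (0.0741), 2 (0.0732) or 3 (0.0514), without WT replicates 1 and 3 together (0.0719) and without the low-count filter (0.138), and Rhoc on leaving out any KO library (0.0597 to 0.0707) or WT replicate 5 (0.0596). Of 25 TGF-beta and BMP genes, 1 was higher and 5 lower, and 1 and 5 adjusted over the list alone (adjusted p = 0.432), with Tgfb1 at -0.46 (SE 0.08). No member of these 6 lists passed over all genes with KO as 1 sample.

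Markers of other cells and tissues varied among the WT libraries. Of 14 brown adipocyte genes, 0 passed (adjusted p = 0.432), with Ucp1 at 94.8 ± 3.40 against 171 ± 179 CPM and Cidea at 54.8 ± 2.53 against 85.2 ± 67.4 CPM. Of 20 general adipocyte genes, 0 passed (adjusted p = 0.641), with Fabp4 at 470 ± 10.1 against 741 ± 458 CPM. Of 18 endothelial genes, 0 passed (adjusted p = 0.720), with Pecam1 at 158 ± 2.13 against 269 ± 135 CPM. Of 19 macrophage genes, 4 were higher and 0 lower, and 5 and 1 adjusted over the list alone (adjusted p = 0.118), with Adgre1 at 0.86 (SE 0.13) and Csf1r at 0.65 (SE 0.10). The abundant macrophage genes Lyz2 and C1qa had 0.23 and 0.20 and did not pass. Of 7 cartilage genes 2 were higher, Comp at 0.67 (SE 0.09) and Chad at 0.96 (SE 0.25), and 2 adjusted over the list alone (adjusted p = 0.106). Of 12 skeletal muscle genes 1 was lower, and 1 adjusted over the list alone (adjusted p = 0.988), Tnnt1 at -0.89 (SE 0.22), while 0 of 9 cardiac muscle genes passed (adjusted p = 0.988). Chad lost its call without KO replicate 2, 3, 4 or 5 (adjusted p 0.0603 to 0.0679) or WT replicate 5 (0.0581), and Tnnt1 without KO replicate 1, 2, 3 or 4 (0.0514 to 0.0576).

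Within 2 Mb of Ovgp1, 44 genes were tested and 4 passed, Ovgp1 included, or 9.09% against 14.3% of all tested genes. Wdr77 (chromosome 3, 105959369 to 105970037), which lies beside Ovgp1, had a log2 difference of -0.68 (SE 0.08, adjusted p = 0.000372). Ppm1j had -0.56 (SE 0.11, adjusted p = 0.00815) and Rhoc -0.26 (SE 0.07, adjusted p = 0.0267; 0.0597 to 0.0707 on leaving out 1 KO library, and 0.0596 without WT replicate 5). None of the 44 passed with KO as 1 sample.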

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

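In groups of 5 libraries, a value was listed where the gap between the highest or lowest library and its nearest neighbour took up most of the group's range. Of 262 groups of values checked, 10 met this rule, and chance alone gives about 1 in 20. Among the WT libraries, replicate 1 stood above the others in Mylk at 1552 CPM, replicate 2 in Dbh at 0.299 CPM and in the fibroblast list at a mean log2 CPM of 6.79, and replicate 4 in Atp5o at 84.9 CPM. Among the libraries labelled KO, replicate 3 stood below the others in Scara5 at 99.9 CPM, Ncam1 at 305 CPM and Cxcl12 at 207 CPM, while replicate 4 stood above them in Uchl1 at 123 CPM and replicate 2 in Errfi1 at 188 CPM. The share of counts of the ribosomal RNA-like gene CT010467.1 was 0.306% in KO replicate 4. The KO values lie in narrow ranges, so a gap that meets the rule there is small.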

How the results depend on the processing

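The fit with KO as 1 sample and the fit without WT replicates 1 and 3 were chosen after seeing the data. Against 2242 genes in the planned fit, 7 passed with KO as 1 sample, 298 with a tested fold of 1.2, 1319 with a replicate block, 4253 with 1 surrogate variable, 4386 without WT replicates 1 and 3, and 6477 with limma-voom and sample weights. Leaving out each library gave 1287 to 2678, lowest without KO libraries. The replicate numbers do not pair the libraries: same-numbered deviations correlated between -0.04 and 0.04, and not every library correlated best with its own number. With the block, 10 lists passed, and Mt1, Errfi1, Fkbp5, Rhoc, Chad, Kcnmb1, Ctla2b, Gm10800, Gm10801 and Gm21738 did not (adjusted p 0.0549 to 0.155). The tested fold of 1.2 gave a gene count alone. Ovgp1 was higher in the libraries labelled KO under each alternative that gave it a value, and of these lost its call with KO as 1 sample (log2 difference 2.39, adjusted p = 0.217; 0.0961 to 0.801 when a WT library was also left out). Leaving out each library gave 2.24 to 2.50. Myh9 was not called under any alternative that gave it a value, turned to -0.065 with limma-voom and -0.048 without WT replicate 2, and ranged from -0.048 to 0.097 on leaving out each library. Against 7 lists, 2 passed with an estimated correlation, 20 without a low-count filter and 15 without WT replicates 1 and 3, and leaving out each library gave 7 to 12. Scores per library passed for 9 lists with either prior count. The surrogate variable varied almost only among the WT libraries, from -0.576 to 0.601, against -0.0223 to -0.0158 in the libraries labelled KO. It thus took up spread of the WT libraries. The cause of these shifts was not tested further, except that summing leaves 1 KO sample.

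Over the other named genes, 2035 of the values recomputed kept their direction and their side of the threshold, 201 lost the call, 98 gained it and 17 changed sign. Of the losses, 77 came with KO as 1 sample. The sign changes were of 6 genes that did not pass in the planned fit. Without the low-count filter Uchl1 was at 0.026 and Star at 0.0016. With the block Ucp1 was at 0.020 and Uchl1 at 0.0036, and with the surrogate variable Ucp1 at 0.084 and Sox17 at 0.039. With limma-voom Ncam1 was at 0.022 and Uchl1 at 0.173, and without WT replicates 1 and 3 Ncam1 was at 0.031, Uchl1 at 0.131 and Star at 0.038. On leaving out each library the ranges were -0.127 to 0.091 for Uchl1, -0.103 to 0.013 for Star, -0.130 to 0.176 for Casq1 and -0.680 to 0.055 for Sox17. No alternative varied the depth.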

Other observations

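The antibody transcripts of the libraries labelled KO had similar profiles. Immunoglobulin variable genes took 1605 to 1907 counts per library labelled KO and 41 to 119 per library labelled WT. Igkv3-2 made up 34.3% to 42.3% of them in each library labelled KO, while the leading gene differed among the WT libraries: Igkv14-126 in WT replicates 2, 3 and 5, Igkv20-101-2 in WT replicate 1 and Igkv3-10 in WT replicate 4. Igkv3-5 varied more among the libraries labelled KO, with 88, 88, 169, 172 and 98 counts in replicates 1 to 5. Of 14 tested sympathetic neuron genes written down after the pattern was seen but before their own values, 6 were higher and 1 lower in the planned test. The most abundant, Cyb561, was the 1 that was lower, at 113 against 147 CPM. Members that did not pass ranged from -0.51 for Hand2 to 0.96 for Chga. Among the 6 that were higher, Ddc, which completes dopamine synthesis, had a log2 difference of 2.04 (SE 0.31). Syt1 had 1.98 (SE 0.32), Scg2 1.83 (SE 0.37) and Prph 1.32 (SE 0.24). Levels of these genes were low, at 2.05 against 0.50 CPM for Ddc and 1.00 against 0.28 CPM for Scg2. None of them passed with KO as 1 sample.

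Gm8730, a processed pseudogene, had 3890 to 4208 counts in the libraries labelled KO and 495 to 578 in those labelled WT. Rplp0 had 17387 to 19236 and 21077 to 27292. Of the summed counts of Gm8730 and Rplp0, Gm8730 took 17.9% to 18.3% in the libraries labelled KO and 1.85% to 2.67% in those labelled WT. Whether the groups differed in how reads were assigned between these genes was not tested. Gm15446 had 62 to 87 and 2 to 7 counts. Nnt had 3 to 18 counts in each of the 10 libraries.

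The tests of the paralogs, the oviduct, the exchange of labels and the variable gene shares were chosen after their results were seen. The tests of copied libraries, plasma cell genes, sympathetic neuron genes and scaling were prompted by the patterns but written down before their own results were seen. Shares of immunoglobulin variable genes, which differ between animals, correlated across genes at 0.985 or more between every 2 libraries labelled KO and at 0.713 or less between WT libraries, which held few such counts. KO pairs were thinned to the counts of each WT pair, 200 times, in draws that cover counting error alone. The median correlations were 0.908 to 0.958, and all 10 WT pairs lay below the lowest 2.5% of draws. Over the variable genes with at least 50 counts 8 of the 10 did, and WT replicates 1 and 3 and replicates 2 and 3 did not. A candidate explanation is that the 5 libraries came from 1 RNA source, either 1 animal or a pool, which these counts do not separate. Repeats of 1 source can also give many calls. When 1 WT library was copied in silico into 5 and compared with the other 4, a median of 4291 genes passed, although no genotype differed. The counts were 4032 to 5592 for 4 of the libraries and 27 for WT replicate 5. The copies were drawn with the small spread of the libraries labelled KO, so they do not show that those libraries are repeats. In 100 splits of the 10 libraries, the real split gave 2242 genes and the highest other 0, so 1 split gave as many. A chance arrangement of independent libraries is argued against, but repeats of 1 source part the libraries in the same way, and an effect of the genotype stays open and untested.

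Higher Ovgp1 in the libraries labelled KO is not what a loss of transcript would give. A rise in chitinase-like paralogs is argued against for those measured: the 5 together differed by 1.53 CPM (SE 1.03; 25.4 ± 1.32 in KO and 23.9 ± 1.90 in WT, SD) while Ovgp1 differed by 16.4 CPM, all scaled to total counts. Most of these paralog counts were of Chid1, at 460 to 669 per library. Paralog reads assigned to Ovgp1 would be counted at Ovgp1, so these values cannot exclude a difference in read assignment. Oviduct of the sampled animals is argued against: Xist had at most 21 counts and the Y-linked genes at least 206 in every library, as in males. The oviduct list had 4 of 10 members tested, with a median log2 difference of -0.35, and Foxj1, Pax8, Epcam, Krt8, Tekt1 and Wnt7a had 0 to 11 counts in both groups. Exchanged group labels stay open: the libraries labelled WT held up to 101 Ovgp1 counts, and a targeted allele may leave transcript behind. Transcription from the targeted allele was not tested, because the counts do not resolve exons.

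The libraries labelled KO may have held lymphoid tissue or sympathetic ganglion from around the vessel. Of 12 plasma cell genes 9 were tested, with a median log2 difference of 0.21 and 2 above all WT libraries. The 14 sympathetic neuron genes had a median of 0.83 and 6 above all WT libraries. Neither met what had been written down for a source of that kind, and neither was ruled out, so tissue taken at dissection and a difference in the aorta itself cannot be told apart. Other size factors moved the median of the lymphocyte list by 0.0083 and that of all genes by 0.0086, so this change did not test scaling.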
